A study of Caenorhabditis elegans with 2 samples.

How the data were processed

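Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA fragments attached to a chosen protein and places them on the genome. The protein was ELT-3, a GATA-type zinc finger transcription factor of the hypodermis (the worm epidermis), carried with a green fluorescent protein tag by the Caenorhabditis elegans strain OP75. That strain has an integrated transgene in an unc-119 mutant background. Per the labels, chromatin came from whole embryos of mixed stage and pooled sex, and 2 biological replicates made up the 1 group. A control is named in the labels, but control data were not analysed here, so no contrast between groups was made.

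Per the authors' listings of each library, a list of peaks and background regions was called at a relaxed threshold for each replicate from its alignments and a control, and another list from both replicates pooled. A list of peaks that passed a threshold on the irreproducible discovery rate (IDR), a measure of rank agreement between replicates, was derived from the pooled list and both replicate lists. Its members are called reproducible peaks below. Each list was deposited on the genome builds ce10 and ce11. The aligner, the peak caller and the IDR threshold are not given in the sources used here. In the deposited lists each region carries a signal value, a score of the caller with no stated scale, and it is the authors' value. The deposited lists also hold a −log10 q-value, which was not used in any test because 534 of the 637 reproducible peaks tie at its highest value, 3.03. The scale of the score differed between lists, so peaks were ranked, filtered and tested by score only within a list, and scores of different lists were compared only through their correlation across matched peaks. Read depth is unknown from peak lists.

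The reproducible list held exactly the 637 regions of highest score in the pooled list of 12702. Reproducible peaks were called on pooled replicates, so the list gives no spread between replicates, and the replicate lists were used for that. Confidence intervals of shares are exact binomial 95% intervals over peaks or genes and cover counting error only.

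Coordinates were read on ce11. The reference was WBcel235 with Ensembl release 115 annotation, which holds 19973 protein-coding genes on the 6 nuclear chromosomes. Chromosome names were matched and every ce11 region ended within its reference chromosome. No reference coordinate was used with the ce10 lists. A gene counted as bound when a reproducible summit lay in its 5′ window, from 1000 bp upstream to 500 bp downstream of the annotated 5′ end. Annotated 5′ ends of trans-spliced genes can lie downstream of the true start of transcription.

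Tests were fixed before the data were examined. Overlap of replicates was the share of the 637 highest peaks of replicate 1 that overlapped, by at least 1 bp, any of the 637 highest of replicate 2, against 10000 random draws from the replicate 2 list (one-sided permutation test). Shares of summits in 5′ windows, and within 200 bp of tRNA, snRNA, snoRNA or rRNA genes, were set against 10000 sets of random positions on the same chromosomes (two-sided permutation tests). Random positions included sequence to which reads may not map. The GATA sequence WGATAR (W is A or T, R is A or G) was searched on both strands within 50 bp of each summit and in windows of equal width centred 500 bp away (exact McNemar test, two-sided, 1 flank per peak). All 2080 6-mers, with reverse complements merged, were tested in the same windows with Fisher's exact test and Benjamini-Hochberg adjustment. Bound genes were counted in 18 gene lists with Fisher's exact test, two-sided, adjusted over the lists, and 2 listed symbols were not matched in the annotation. Median signal with and without WGATAR was compared with 100000 permutations. Signal correlation used reproducible peaks with a summit within 100 bp in each replicate list, with no p-value, since peaks are not independent replicates.

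Named genes followed a fixed rule. It took the genes at the 20 reproducible peaks of highest signal, elt-3 and unc-119, and up to 4 members per list with the highest peaks (for a list with none, up to 2 in alphabetical order). Because 19 of those 20 peaks were mitochondrial, genes at the highest nuclear peaks were added after their values were seen. So were the split of summits by annotation, the sequences GACGCAG, GAGAGA and CTTATCA, and the separate counts per class of RNA gene.

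Alternatives covered the genome build, overlap rule, window sizes, motif, background, a stricter signal threshold (the 318 highest peaks), peaks near elt-3 or unc-119, and each replicate alone, taken as its 637 highest peaks. Nuclear peaks alone, and background windows of equal GC content (10 per peak, outside coding exons), were added after the data had been seen. The 6-mer test was tested on simulated data with 637 windows. It recovered 68% of 6-mers planted in 5% of windows and 98% of those planted in 10%, and called 0 in 10 runs with nothing planted. Both sides of the simulated comparison were windows at random nuclear positions. These runs therefore do not cover calls that come from the difference in G and C content between summits and flanks. The gene-list test recovered 30.5% of lists simulated with an odds ratio of 5 and 93% of those with an odds ratio of 20. False calls numbered 3 in 200 runs with nothing planted, 7 in the 200 runs with an odds ratio of 5 and 12 in the 200 with an odds ratio of 20. Genes were simulated as bound independently, whereas 81 nuclear summits lay in windows of 2 or more genes. False calls can thus be more frequent than simulated for lists with neighbouring members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.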

Results

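Binding of tagged ELT-3 was mapped in mixed-stage embryos from 2 biological replicates of the same strain. The labels give no second condition, so the comparisons are between replicates, and between peaks and the rest of the genome. The replicate lists held 19168 regions for replicate 1 and 26381 for replicate 2 at the relaxed threshold. The reproducible list held 637 peaks on ce11 and 633 on ce10, with a median width of 380 bp on both builds. On ce11, 614 of these peaks were nuclear and 23 were mitochondrial.

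The highest nuclear peak lay at the cuticle collagen gene dpy-14, with its summit 124 bp upstream of the 5′ end (chromosome I, 6843366 to 6843604, intergenic) and a signal of 233. It was the highest nuclear peak in the replicate 1 list, at 142, and in the replicate 2 list, at 91.8. Of the 637 highest peaks of replicate 1, 351 overlapped any of the 637 highest of replicate 2, or 55.1% (exact 95% interval 51.1 to 59.0%). Random draws from the replicate 2 list gave 2.69% on average (one-sided permutation test, p = 0.0001, the smallest the draws can give). Signal over the 603 reproducible peaks matched in both lists had a Spearman rho of 0.38 and a Pearson r of 0.58 on the log10 scale, across peaks. These peaks are those of highest pooled signal, a choice that narrows the range and can lower the correlation, and over the 4734 replicate 1 peaks matched in replicate 2, not chosen by pooled signal, rho was 0.49. A stricter choice by pooled signal, the 318 highest peaks, also had a higher rho, at 0.44. Over the 584 nuclear reproducible peaks matched in both lists, rho was 0.33 and r was 0.35, an alternative added after the data had been seen.

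**Figure D1:**
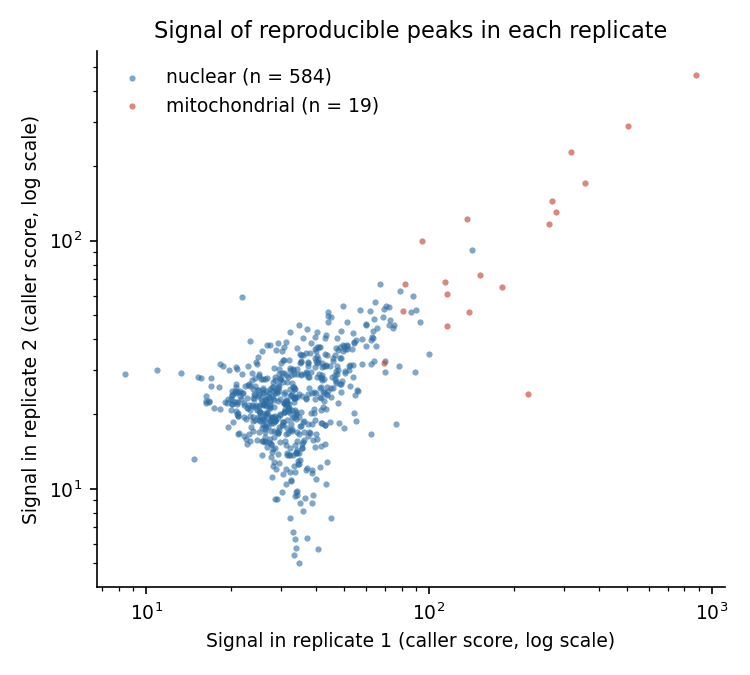
Signal of each reproducible peak in the replicate 1 list (x axis) and the replicate 2 list (y axis), in the caller's score on log scales. Points are the 584 nuclear and 19 mitochondrial peaks matched in both lists, and the mitochondrial peaks include the highest values in both replicates.

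Of the 20 peaks of highest signal, 19 were mitochondrial. The highest, with a signal of 1298, had its summit at position 310 of the mitochondrial genome in the coding sequence of ND6, and another, with a signal of 541, lay in COX3 at position 5789. Both genes encode subunits of respiratory chain complexes. Among nuclear peaks, those after dpy-14 included a summit 600 bp upstream of egg-5 (chromosome I, 4171999 to 4172378, signal 148), which was also within 200 bp of a small structural RNA gene, and summits in introns of arrd-10 (chromosome II, 12942617 to 12942784, signal 140.0), mom-1 (chromosome X, 6296507 to 6296697, signal 139) and pck-2 (chromosome I, 7867122 to 7867268, signal 138). These nuclear genes other than dpy-14 were chosen after their values were seen. At elt-3 itself (chromosome X, 13934874 to 13941216), no reproducible summit fell in the 5′ window. Summits lay in its introns 2479 bp and 4723 bp downstream of the 5′ end, with signals of 75.0 and 48.1, and upstream at 14305 bp and 17262 bp. Whether the integrated transgene of the strain added to peaks at this locus cannot be told from peak lists. No reproducible summit lay within 20 kb of unc-119, whose rescue commonly marks transgenes.

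Nuclear summits lay mostly outside coding sequence. Of all 637, mitochondrial summits included, 46.5% (exact 95% interval 42.5 to 50.4%) were in the 5′ window of a protein-coding gene, against 27.8% of random positions (two-sided permutation test, p = 0.0002, the smallest the sets can give). For nuclear summits alone, an alternative added after the data had been seen, these shares were 45.1% and 25.7%. Among the 614 nuclear summits, 374 were intergenic (60.9%, against 32.8% of all positions on those chromosomes) and 148 were in introns (24.1% against 34.2%). Coding exons held 12 (1.95% against 24.5%, exact binomial test, adjusted p = 9.6e-56 over the 7 annotation classes). The nuclear summits fell in the windows of 358 genes, and 81 lay in windows of 2 or more genes. A further 214 summits, 34.9%, were more than 2000 bp from any annotated protein-coding 5′ end.

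**Figure D2:**
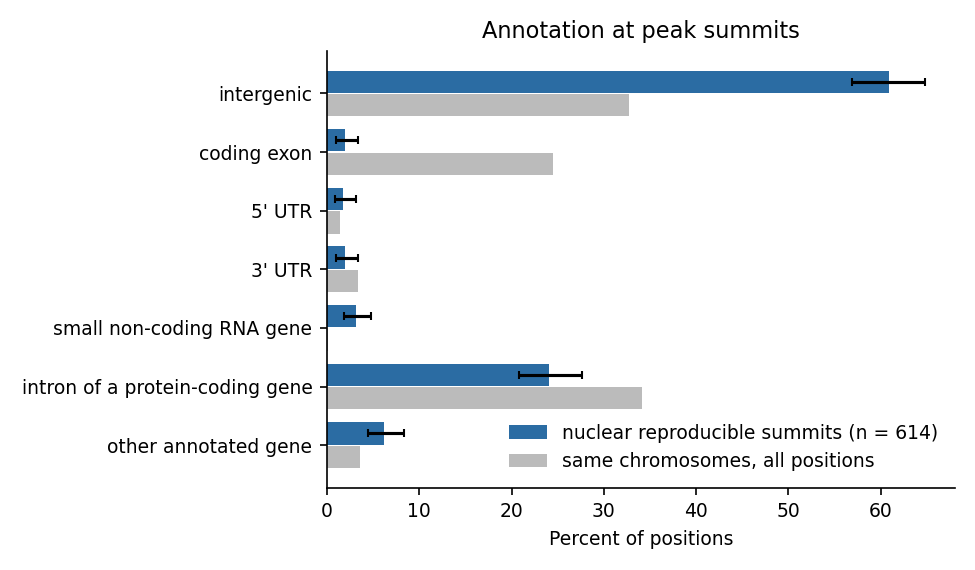
Percent of the 614 nuclear reproducible summits in each annotation class (blue, with exact 95% intervals) and of all positions on the same chromosomes in proportion to peaks (grey). Coding exons held 1.95% of summits and 24.5% of positions.

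The sequence recognised by GATA factors was more frequent at summits than beside them. WGATAR was found within 50 bp of 242 of the 637 summits, or 38.0% (exact 95% interval 34.2 to 41.9%), against 20.6% in the flanks (exact McNemar test, two-sided, p = 7.9e-13). The dpy-14 summit was among them. The narrower TGATAA stood at 23.9% against 8.32% (exact McNemar test, p = 2.8e-15). The control sequence WGTAAR, a rearrangement of the same bases, went the other way, at 12.9% against 22.2% (exact McNemar test, p = 1.2e-05). Nuclear summits were richer in G and C, at 44.8% against 35.5% at 500 bp. Against windows of equal GC content, added after the data had been seen, WGATAR was at 38.0% against 14.2% (Fisher's exact test, p = 8.2e-44) and WGTAAR at 12.9% against 15.4% (p = 0.093, Fisher's exact test). Median signal was 54.2 with WGATAR and 53.4 without, a difference of 0.0057 on the log10 scale that did not pass the test (permutation test, two-sided, p = 0.64).

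In the search over all 2080 6-mers, 381 were more frequent at summits and 246 less frequent (Fisher's exact test, adjusted p under the 0.05 threshold). Against windows of equal GC content 238 were more frequent, of which 167 were among the 381, and among the 318 highest peaks 221 were. The leading 6-mer against the flanks was GAGAGA, in 26.5% of summit windows against 5.11% of flank windows (Fisher's exact test, adjusted p = 6.3e-36). CGTCTC followed at 19.3% against 2.28%, and ACGCAG at 16.2% against 1.41%. CTTATC, the reverse complement of GATAAG, ranked 5 at 19.2% against 3.06% (Fisher's exact test, adjusted p = 2.1e-28). Against windows of equal GC content the order differed. CTTATC was at 3.09% there (Fisher's exact test, adjusted p = 3.0e-45) and TGATAA at 5.67% (adjusted p = 1.4e-41, Fisher's exact test), both with smaller p than GAGAGA at 9.01% (adjusted p = 1.9e-30, Fisher's exact test), and ACGCAG was at 4.57%. The leading less frequent 6-mer against the flanks was AAAAAT, at 18.7% against 51.6%.

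**Figure D3:**
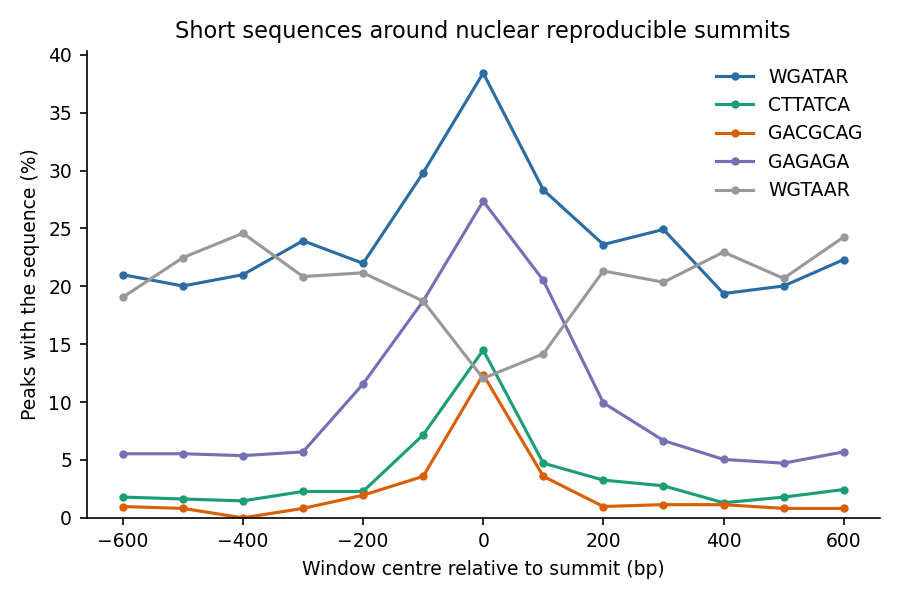
Percent of the 614 nuclear reproducible peaks (y axis) with each sequence, on either strand, in windows reaching 50 bp to each side of positions up to 600 bp from the summit (x axis). WGATAR, CTTATCA, GACGCAG and GAGAGA are highest at the summit, and the control WGTAAR is lowest there.

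Hypodermal gene groups held few bound genes, and none of their lists passed the test over the 18 lists. A list with a raised share can fail this test, which recovered 30.5% of lists simulated with an odds ratio of 5. Of 175 cuticle collagen genes 7 were bound, or 4.0% against 1.77% of other genes (Fisher's exact test, odds ratio 2.31, p = 0.039, adjusted p = 0.23). The odds ratio was 1.52 without replicate 1 (5 bound, Fisher's exact test, p = 0.39) and 2.06 without replicate 2 (p = 0.13, Fisher's exact test), 3.04 with the window cut to 500 bp upstream (p = 0.011, Fisher's exact test, adjusted p = 0.098), and against genes matched on upstream distance p was 0.074 (permutation test). The 4 with the highest signal were dpy-14, dpy-17 (249 bp upstream, 67.0), dpy-10 (233 bp upstream, 57.6) and dpy-3 (178 bp upstream, 53.4), and all but dpy-10 held WGATAR at the summit. The dpy-17 peak had a signal of 57.0 in the replicate 1 list and no summit within 100 bp in the replicate 2 list. The summit of another, col-85, lay inside a small structural RNA gene and held no WGATAR. The summits of the remaining bound collagens, col-121 and dpy-2, held none either. Of 24 osmotic and epidermal antimicrobial peptide genes 3 were bound (Fisher's exact test, odds ratio 7.88, p = 0.0087, adjusted p = 0.079). The antimicrobial peptide genes nlp-31 and nlp-34 shared a peak with a signal of 110.2, whose summit lay 24 bp upstream of nlp-31. The third was gpdh-1, an enzyme gene of glycerol synthesis induced by osmotic stress, at 60.2. That list passed with the window extended to 2000 bp upstream (Fisher's exact test, adjusted p = 0.025), among the 318 highest peaks (adjusted p = 0.0075, Fisher's exact test) and without replicate 1 (adjusted p = 0.0092, Fisher's exact test). It did not pass with the window cut to 500 bp upstream (Fisher's exact test, adjusted p = 0.26), without replicate 2 (Fisher's exact test, adjusted p = 0.069), against genes matched on upstream distance (permutation test, adjusted p = 0.19) or with each peak given only to the nearest gene, which left 2 bound (Fisher's exact test, odds ratio 3.09, adjusted p = 0.54). Among hypodermal transcription factors 1 of 22 was bound, the moulting regulator nhr-23, with a summit 971 bp upstream. Among collagen-processing enzymes 1 of 12 was bound, the protease gene dpy-31, and among apical matrix genes 2 of 52, lpr-3 and noah-1. With each peak given only to the nearest gene, 5 of 52 apical matrix genes were bound (Fisher's exact test, odds ratio 3.63, p = 0.016, adjusted p = 0.11). Collagens then stood at 11 of 175 (Fisher's exact test, odds ratio 2.30, p = 0.018, adjusted p = 0.11). Hypodermal transcription factors were at 2 of 22, hedgehog-related and patched-related genes at 2 of 86 (odds ratio 0.81) and junction genes at 0 of 21. By the 5′ window, no gene was bound among 12 GATA factor genes (egl-18 and egl-27 among them, although a summit with WGATAR and a signal of 77.5 lay in an intron of egl-27 on chromosome II at 6842869), 21 junction and fusion genes (aff-1 and ajm-1) and 86 hedgehog-related and patched-related genes (che-14 and grd-1).

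Genes of cytoplasmic ribosomal proteins were the only list that passed the planned test. Of 79 genes 20 were bound, or 25.3% (exact 95% interval 16.2 to 36.4%) against 1.70% of other genes (Fisher's exact test, odds ratio 19.6, adjusted p = 1.3e-16). With each peak given only to the gene with the nearest 5′ end, 11 of 79 were bound, or 13.9% (Fisher's exact test, odds ratio 5.57, adjusted p = 0.00027), since several of these peaks lay nearer a neighbouring gene, as with rps-12 and ska-3 or rps-20 and ekl-4, pairs chosen after their values were seen. Those with the highest signal were rpl-3 (chromosome III, 3867497 to 3867655, summit 288 bp upstream, 127), rpl-35 at 102, rpl-1 at 100.5 and rpl-20 at 88.9, all intergenic and without WGATAR at the summit. The remaining lists did not pass. Among histone genes 3 of 80 were bound, with his-67 and his-68 sharing a peak at 120.4 and his-37 at 55.5. Both bound proteasome genes of 33 were rpn-3 and rpn-6.1, both bound muscle genes of 35 were unc-112 and cpn-3, and both bound genes of 118 in glutathione and xenobiotic metabolism were ugt-26 and ugt-19. The intestinal list had 1 of 54, cpr-9, whose summit was also near a small structural RNA gene, and the germline list 1 of 30, cgh-1. None was bound among 22 pharyngeal genes (ceh-22 and ceh-34 among them), 34 neuronal genes (cat-2 and cha-1) and 35 ciliary genes (bbs-1 and bbs-2).

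**Figure D4:**
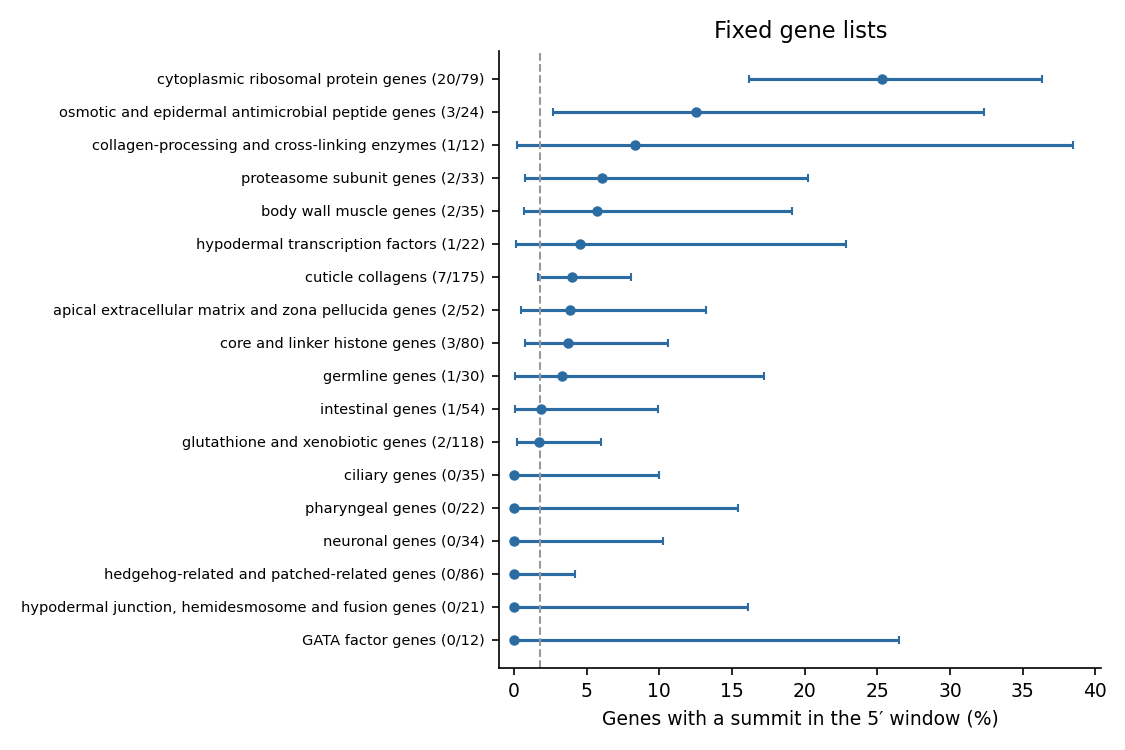
Percent of genes in each list with a reproducible summit in the 5′ window (points, with exact 95% intervals, and bound and listed genes in brackets). The dashed line is the 1.79% of all 19973 nuclear protein-coding genes, and the intervals of the ribosomal protein list, 16.2 to 36.4%, and of the osmotic and antimicrobial list, 2.66 to 32.4%, lie above it.

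Summits were also frequent at genes of small structural RNAs, a usual background of ChIP. Within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene lay 70 of 637 summits, or 10.99% (exact 95% interval 8.67 to 13.7%), against 2.19% of random positions (two-sided permutation test, p = 0.0002, the smallest the sets can give). For the 614 nuclear summits these shares were 9.77% and 0.55%. By class, 28 nuclear summits lay near tRNA genes, 23 near snoRNA genes and 9 near snRNA genes, where random positions gave 1.81, 1.17 and 0.35, and 0 lay near nuclear rRNA genes, where 0.12 was given by chance. On the X chromosome 53 genes were bound, or 14.8% of bound genes, where 13.7% of all genes lie on X (Fisher's exact test, two-sided, p = 0.53). That test counts genes and not peaks. Reproducible peaks ran from 3.97 per Mb on chromosome V to 9.09 per Mb on chromosome I, with 7.34 on X, a spread that was not tested.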

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

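Alternatives using nuclear peaks alone or windows of equal GC content were chosen after seeing the data. Of 65 alternatives for the main results, 56 kept the direction and side of the threshold, or a count within 1.5 times. Direction changed in 2. The control sequence WGTAAR in place of WGATAR was at 12.9% of summits against 22.2% in the flanks (exact McNemar test, p = 1.2e-05). A control without any difference was thus not seen against the flanks, which held less G and C than summits. Against windows of equal GC content, at 15.4%, the difference did not pass (Fisher's exact test, p = 0.093). Log10 signal with WGATAR minus without, which did not pass in either case, was −0.013 among the 318 highest peaks, and the cause was not tested. The rho of signal rose to 0.49 over all replicate 1 peaks matched in replicate 2. Enriched 6-mers numbered 221, and depleted ones 135, among the 318 highest peaks, where fewer windows were tested, and 238 were enriched against windows of equal GC content. The count of gene lists passing went from 1 to 2 with windows from 2000 bp upstream and also among the 318 highest peaks, and was 1 to 2 with either replicate left out. The added list was the osmotic and antimicrobial list, and the cause was not tested. Of 144 alternatives for single lists, 116 kept direction and side, 3 newly passed and 25 changed direction, none of those 25 passing before or after. With windows from 500 bp upstream the odds ratio was 0 for hypodermal transcription factors and the collagen-processing, intestinal and germline lists, and 1.24 for glutathione genes. With windows from 2000 bp it was 1.96 for junction genes, 2.38 for ciliary and 0.74 for intestinal genes. With the nearest gene alone it was 3.09 for GATA factor genes, 0 for intestinal and 0.87 for histone genes. Among the 318 highest peaks it was 0 for hypodermal transcription factors and the collagen-processing, apical matrix, intestinal, muscle and germline lists, and 1.09 for glutathione genes. With either replicate left out it was 0 to 5.25 for collagen-processing, 0 to 1.09 for intestinal, 0 to 1.70 for muscle, 0 to 1.99 for germline and 0.99 to 1.34 for glutathione genes, and 0 in both cases for hypodermal transcription factors. The cause was not tested. Leaving out either replicate gave promoter shares of 45.5 to 48.4%, WGATAR shares of 34.1 to 38.1% and shares near small RNA genes of 10.05 to 10.67%. Read depth is unknown, so which unlisted genes lacked enough reads cannot be said.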

Other observations

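The tests of mitochondrial peaks, of motif position and of the 154 peaks with the highest signal, and all class comparisons in the next paragraph, were chosen after the related results were seen.

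The GATA sequence was unevenly spread over nuclear peaks. WGATAR was at 46.0% of the 337 summits outside 5′ windows and 29.2% of the 277 inside them (Fisher's exact test, adjusted p = 0.00017 over 40 comparisons of sequence and class). In introns it was at 51.4% of 148 summits, against 34.3% of the others (Fisher's exact test, adjusted p = 0.0014). Of the 60 summits near small structural RNA genes 5 held it, or 8.33% against 41.7% elsewhere (Fisher's exact test, adjusted p = 3.3e-06). Flank and equal-GC windows were not compared by class, so differences in base composition between classes were not separated from these shares. On X, WGATAR was at 34.6% of summits against 39.5% on autosomes (Fisher's exact test, adjusted p = 0.42), while the longer CTTATCA, chosen from these data, was in 6 of 130 peaks, or 4.62%, against 17.1% (Fisher's exact test, adjusted p = 0.00061). GACGCAG and GAGAGA occurred together, with GACGCAG in 22.02% of peaks that held GAGAGA and 8.74% of those that did not (Fisher's exact test, adjusted p = 0.00017).

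Genes of the broad annotation class ncRNA had 111 nuclear summits within 200 bp, where random positions gave 21.7. Pseudogenes had 3, where random positions gave 21.8. Within 20 kb of elt-3 lay 4 reproducible summits, as many as 0.22% of genes had, and 15 regions of the pooled list. A contribution of the integrated transgene to these counts was not tested, so they cannot be read as binding at the native locus alone.

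Ribosomal protein genes stood out among the lists although none of the hypodermal lists passed. Compact upstream regions do not account for all of it. Random genes matched on the distance to the next upstream gene gave 1.63 bound genes on average where 20 were observed (permutation test, p = 0.0002, the smallest the sets can give). With each peak given only to the nearest gene the count was 11 of 79, so a part from close neighbours stays open. General enrichment of active promoters without GATA sites may contribute. WGATAR was at 10.5% of the 19 ribosomal protein peaks and 30.6% of other peaks in 5′ windows, but the difference did not pass (Fisher's exact test, p = 0.070). Against all other nuclear peaks, where 39.3% held it, the difference passed (Fisher's exact test, odds ratio 0.18, adjusted p = 0.039 over the 40 comparisons), but peaks in 5′ windows held it less often in general. That explanation stays open, as does binding by ELT-3 through other proteins, which was not tested.

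In 378 of 614 nuclear peaks no WGATAR lay within 50 bp of the summit. A candidate explanation is that summits were placed off the site. From 51 to 190 bp, 185 of the 378, or 48.9%, held WGATAR, against 47.6% in the flanks (exact McNemar test, p = 0.77). The rest held none within 190 bp of the summit, which argues against off-site summits as the whole cause. Peaks near the detection limit might also lack the motif. As the whole cause, lower signal within this list is argued against by the 154 nuclear peaks with the highest signal (68.0 to 233). Of these 39.0% held WGATAR (exact 95% interval 31.2 to 47.1%), against 38.3% of the rest, while most would be expected to hold it. A part stays open, since the 153 with the lowest signal held it at 32.7% and the median log10 signal with the motif minus without was 0.010 over all nuclear peaks (permutation test, p = 0.32). Other sequences in place of GATA sites, GACGCAG or GAGAGA, were in 36.2% of these peaks and 29.7% of peaks with WGATAR (Fisher's exact test, p = 0.096). These were not more frequent inside 5′ windows than outside them (GACGCAG 12.3% and 12.5%, GAGAGA 25.6% and 28.8%). For the narrower TGATAA the differences passed, at 13.2% of peaks with GACGCAG against 26.0% of the others (Fisher's exact test, adjusted p = 0.039) and 17.9% of peaks with GAGAGA against 26.9% (Fisher's exact test, adjusted p = 0.048), in the direction of this explanation. For the longer CTTATCA they did not pass. It was at 11.8% against 14.9% by GACGCAG (Fisher's exact test, adjusted p = 0.67) and 13.7% against 14.8% by GAGAGA (Fisher's exact test, adjusted p = 0.82). Other sequences stay open, since the test on WGATAR, which defines these peaks, did not pass. A part for off-site summits and a part for low signal stay open, because those differences did not pass.

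The 23 mitochondrial peaks could come from mitochondrial DNA copies not matched by the control, which would cover most of that genome. They covered 47.01% of it, and nuclear peaks covered 0.23% of the nuclear genome. The mitochondrial share was short of the 50% set for that test. Reproducible regions were at most 380 bp wide, which limits what 23 peaks can cover. Falling short of 50% therefore does not argue against this explanation. Binding at GATA sites in mitochondrial DNA was tested by shifting the summits around the circle. WGATAR was within 50 bp of 26.1% of them and 30.6% of shifted positions (exact test over all shifts, one-sided, p = 0.78). Control data were not analysed here, which keeps both open.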
